A study of Homo sapiens with 4 samples.

How the data were processed

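MYC ChIP-seq peak tables of OVCAR3 and MCF7 cells were analysed. Per the labels' protocols, both lines were grown with 10% serum, and proteins were crosslinked with a 5 mM imidoester crosslinker for 30 min and then with 1% formaldehyde for 10 min. Chromatin was sheared to fragments of 200 to 600 bp and precipitated with an antibody to c-MYC, and libraries were read as single ends of 75 bases. The labels put the 4 samples into 4 groups, a MYC ChIP and an input library for each line, with 1 library in each. Peak tables were used for the 2 ChIP samples, and the 2 input libraries entered only through the background that the peak caller had taken from them.

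Per the submitters' processing notes, the software included CASAVA, FastQC, Bowtie2 2.3.5.1 and MACS2 2.2.6, and the genome build was GRCh37 (hg19). The settings of the peak caller, the handling of duplicate reads and any removal of problem regions were not given in the sources used here. The layout of the deposited tables, per the file headers, is that of MACS2. The deposited pileup is a signal, the height of stacked ChIP fragments at the peak summit. The deposited −log10 p and −log10 q values measure each peak against the local input background. The deposited fold enrichment is the ratio of the pileup to that background with 1 added to both, which is what the values show when p is recomputed from them (below). No peak had a −log10 q under 2, so the tables hold peaks with q below 0.01 only. Since each table came from 1 ChIP library, there were no replicates to compare.

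From these values the local input background at each summit was recovered as the pileup plus 1, divided by the fold enrichment, minus 1. A Poisson probability recomputed from the pileup and this background was within 0.05 of the deposited −log10 p for 100% of OVCAR3 peaks and 97.9% of MCF7 peaks. Pileups were whole numbers in OVCAR3 and multiples of 0.872 in MCF7 (tolerance 0.02 of a read), so that the larger library of each pair had been scaled down to the smaller. Dividing by this step gave whole ChIP reads at each summit. The ratio of ChIP to input reads, from these steps, was 0.876 in OVCAR3 and 1.15 in MCF7. MACS2 takes no background below its genome average. If the caller had used its preset human genome size and a fragment length equal to the smallest peak width (200 bp in OVCAR3, 213 bp in MCF7), the lowest background would correspond to at most 14700000 ChIP and 16800000 input reads in OVCAR3 and to 27800000 and 24200000 in MCF7. These settings are not given in the sources used here. The input level is known at peaks only and is given relative to its median over all peaks of the line, 3.16 reads in OVCAR3 and 3.00 in MCF7. Input levels are in reads at the depth of the smaller library of each pair, so those of OVCAR3 are input reads scaled by 0.876. Summit reads of MCF7 are unscaled, so dividing them by the input level does not give the fold enrichment. Because of the floor that the caller sets, relative levels under 0.345 in OVCAR3 and 0.636 in MCF7 cannot be seen. Since input varies with the amount of DNA, a segment present in many copies gives more reads at every site, and weaker enrichment then passes the threshold.

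Peaks of both lists were called shared when they overlapped by at least 1 bp. The overlap was set beside 1000 random placements of the MCF7 peaks on their own chromosomes outside centromeric, stalk and variable bands. Peaks were ranked within each list by −log10 q and then fold enrichment. Overlapping peaks were paired with the strongest partner, and each MCF7 peak was used once. Peaks were counted in bins of 5 Mb and in chromosome arms. A bin was called a high-input segment of a line when it held at least 8 of its peaks and their median input was at least 3 times the median of the line. Ratios compare the share of all MCF7 peaks that lay in a region with the same share of OVCAR3 peaks. Shares have exact (Clopper-Pearson) 95% intervals, read counts exact Poisson intervals, and ratios of shares exact binomial intervals. These cover counting error only, and reads may include PCR copies, so they are no measure of how another culture of the same line would vary.

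The comparisons, most alternatives and the rule for named peaks were set before the data were examined. By that rule the text names, for each line, the 12 highest-ranked peaks, the 8 highest-ranked peaks with no peak of the other line within 10 kb of the summit and the 5 with the largest fold enrichment, and the 12 shared peaks with the best value for the worse of both ranks. Peaks in 2q32.2 were added in place of promoter peaks of GLS. The arms and segments described were chosen after the data had been seen. Alternatives tried were −log10 q of at least 5 and of at least 10, the 1000 strongest peaks of each list, merging of peaks within 500 bp, a reciprocal overlap of 0.5, summits within 200 bp, peaks within 1 kb and bins of 10 Mb. Added after the data had been seen were fold enrichment of at least 5, leaving out the high-input segments, a segment threshold of 2 times the median, and random shifts within 500 kb.

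No genome or gene annotation of hg19 was used. The gene table used here is that of GRCh38.p14, and positions were not converted between builds, so only the gene ID and the neighbours of GLS were taken from it. For this reason the planned results on promoters, E-box sequences, glutamine metabolism genes and gene lists were not made. Cytogenetic bands of hg19 came from the R package circlize 0.4.16. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The overlap code was tested on simulated data: of 4868 simulated peaks 2000 were planted as overlaps and 2007 were found, the remainder being chance overlaps.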

Results

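MYC binding was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in 2 human carcinoma cell lines. OVCAR3 is an established line of high-grade ovarian carcinoma, and MCF7 is an established line of estrogen receptor positive breast carcinoma. Each line had 1 MYC ChIP library and 1 library of input DNA, the sheared chromatin before immunoprecipitation, which made 4 libraries. There were no replicates, so no p-value was made between the lines. Intervals are 95% and cover counting error only. The peaks had been called by the authors in each line on its own, and the fold enrichment and q of a peak are the authors' values. Positions are those of hg19 (GRCh37). Peaks are named by position and cytogenetic band, since no gene annotation of that build was used here. Read totals were not used here, and depth was read from the peak tables. Input levels are in reads at the depth of the smaller library of each pair, while ChIP reads at summits are unscaled. The lowest input level at any peak was 1.09 reads in OVCAR3 and 1.91 reads in MCF7, a ratio of 1.76. This level depends on the fragment length and on the smaller library of each pair, the ChIP in OVCAR3 and the input in MCF7. The ratio is therefore only a rough guide to depth and does not compare libraries of the same kind. The ratio of ChIP to input reads was 0.876 in OVCAR3 and 1.15 in MCF7.

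OVCAR3 had 4868 MYC peaks and MCF7 had 5979. The peaks were narrow in both lines, with a median width of 296 bp in OVCAR3 (quartiles 236 and 392) and 315 bp in MCF7 (254 and 418). The median enrichment over input was 6.18-fold in OVCAR3 (quartiles 4.94 and 8.11) and 5.92-fold in MCF7 (4.75 and 7.66), and the highest was 37.5-fold and 35.6-fold. A typical peak rested on few reads, with a median of 25 ChIP reads at the summit in OVCAR3 and 30 in MCF7. The largest q in the lists was 0.00974 in OVCAR3 and 0.00967 in MCF7. At a −log10 q of at least 10, 2551 OVCAR3 and 2954 MCF7 peaks were left.

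The strongest OVCAR3 peak by q lay in 17q21.31 (chromosome 17, 41738800 to 41740384), with 230 reads at its summit (interval 201 to 262) and 18.6-fold enrichment. Next came a peak in 17p11.2 (chromosome 17, 17109489 to 17110298) with 33.6-fold enrichment and one in 20q11.23 (chromosome 20, 37063362 to 37064180) with 37.5-fold enrichment, the highest of this line. The other 9 of the 12 strongest OVCAR3 peaks lay in 20p11.23, 19q13.12 (2 peaks), 3p22.1, 19q13.42, 3p21.31, 19q12, 17q23.3 and 11q14.1. The strongest MCF7 peak lay in 17q23.3 (chromosome 17, 61850897 to 61851580), with 249 reads at its summit (interval 219 to 282) and 31.2-fold enrichment. The MCF7 peak with the highest enrichment, 35.6-fold, lay in 10q24.32 (chromosome 10, 103911853 to 103912761). A peak in 7p13 (chromosome 7, 45025639 to 45026711) followed with 34.6-fold enrichment. The other 9 of the 12 strongest MCF7 peaks lay in 20q11.23, 12q14.2, 8q23.1, 22q11.21, 6p22.3, 17q22, 12q14.1, 2q37.1 and 17q21.33. The 5 largest enrichments of OVCAR3 also included 6p21.32 (chromosome 6, 32936288 to 32936759) with 32.9-fold, and those of MCF7 included 6p22.3 with 31.5-fold and 22q11.21 with 31.0-fold.

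The next comparison asked which MYC sites the ovarian and the breast line had in common. The strongest sites were mostly shared: 9 of the 12 strongest OVCAR3 peaks and 12 of the 12 strongest MCF7 peaks overlapped a peak of the other line, as did 90 and 87 of the 100 strongest. Over the whole lists, 2159 OVCAR3 peaks (44.4%, interval 42.9 to 45.8) and 2166 MCF7 peaks (36.2%, interval 35.0 to 37.5) overlapped the other list by at least 1 bp. Placing the MCF7 peaks at random on their chromosomes 1000 times gave a mean of 9.99 overlapped OVCAR3 peaks, with a highest value of 20. Such placements give only the overlap that comes from peak number and width. They were not matched on open promoters, which both lists may favour, so they overstate how far the overlap is particular to MYC. The share rose with peak strength, from 23.6% in the weakest decile to 77.8% in the strongest decile of the OVCAR3 list and from 14.5% to 74.9% in MCF7. Median enrichment was 6.90-fold at shared and 5.77-fold at unshared OVCAR3 peaks, and 7.20-fold and 5.43-fold in MCF7.

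**Figure D1:**
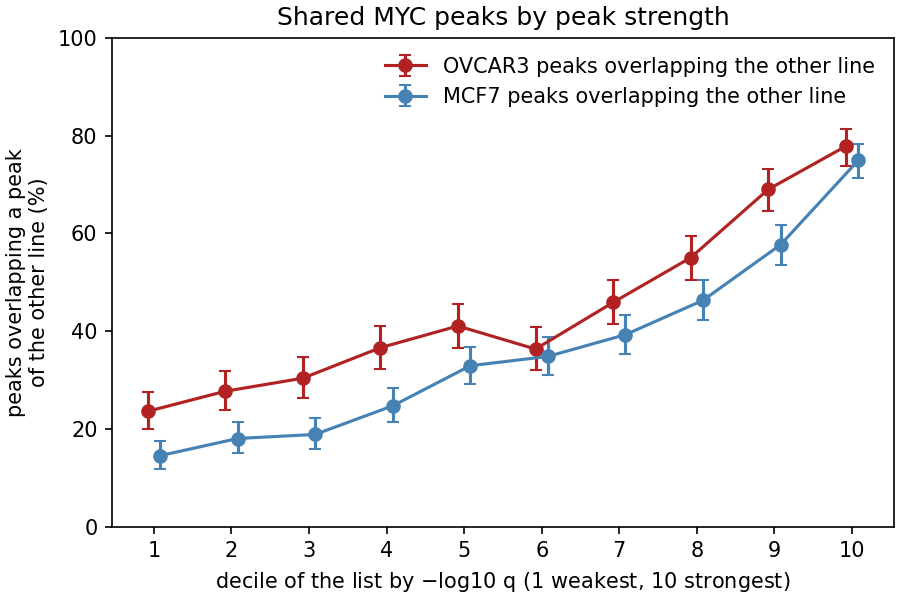
The x axis gives deciles of each peak list by −log10 q, from 1 (weakest) to 10 (strongest), and the y axis the percentage of peaks that overlapped a peak of the other line by at least 1 bp, with 95% exact binomial intervals (counting error only). The share was 23.6% in the weakest and 77.8% in the strongest decile of OVCAR3 (red), and 14.5% and 74.9% in MCF7 (blue).

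The site ranked highest in both lines was the peak in 20q11.23, at rank 3 in OVCAR3 and rank 4 in MCF7, with 37.5-fold and 30.3-fold enrichment and summits 9 bp apart. The peak in 17q23.3 had 27.3-fold enrichment in OVCAR3 and 31.2-fold in MCF7, with summits 2 bp apart. In 12q14.1 (chromosome 12, 58165585 to 58166087 in OVCAR3) the values were 24.4-fold and 13.2-fold, and in 7p13 (chromosome 7, 45025728 to 45026701 in OVCAR3) 26.7-fold and 34.6-fold. The other 8 of the 12 best-ranked shared sites lay in 8q23.1, 3q22.1, 20p11.23, 9p13.3, 21q22.3, 17q11.2, 5q35.2 and Xq28. Across 2119 pairs of overlapping peaks the summits were a median of 42 bp apart, and 78.4% were within 100 bp. The MCF7 to OVCAR3 ratio of enrichment had a median of 1.04 over these pairs (quartiles 0.777 and 1.38). Enrichment was at least 2 times higher in OVCAR3 at 106 pairs and in MCF7 at 148. Shared peaks had a median of only 30 ChIP reads at the summit in OVCAR3 and 34 in MCF7. Counting error was not weighed for these pairs, so they are not shown to differ between the lines. Spearman's rho of enrichment across the pairs was 0.389, where pairs are sites of the same libraries and not independent replicates.

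Strong sites of a single line were fewer. No MCF7 peak lay within 10 kb of 2218 OVCAR3 summits (45.6%), and no OVCAR3 peak within 10 kb of 3210 MCF7 summits (53.7%), but among the 100 strongest peaks only 8 OVCAR3 and 12 MCF7 peaks stood alone in this way. The 8 strongest of OVCAR3 lay in 17q21.31, 19q12, 19q13.12, 20p12.2, 2q32.1, 21q21.3, 11q14.1 and 12p12.1. Of these, 2 lay in segments of high OVCAR3 input, 19q12 with 10.7-fold enrichment at an input level of 19.5 reads and 11q14.1 with 6.82-fold at 22.6 reads. Input was also more than 2 times the median of 3.16 reads at 17q21.31 (11.4 reads), 12p12.1 (7.89 reads) and 19q13.12 (7.71 reads). The peak in 2q32.1 (chromosome 2, 183533374 to 183533789) had 90 reads and 25.1-fold enrichment, the one in 20p12.2 (chromosome 20, 11861370 to 11861773) 101 reads and 22.6-fold, and the one in 21q21.3 (chromosome 21, 28215235 to 28215628) 79 reads and 22.04-fold. Of the 8 strongest MCF7 sites, 4 lay in 20q13.12, 2 in 20q13.2, and the others in 7p22.3 and 8q24.3. The 8q24.3 peak (chromosome 8, 145733500 to 145734109) had 84 reads and 18.6-fold enrichment, and the 7p22.3 peak (chromosome 7, 1595534 to 1596251) 103 reads and 15.1-fold. The 4 peaks in 20q13.12 had between 256 and 338 reads but only 4.64-fold to 5.47-fold enrichment, at input levels of 46.0 to 62.0 reads. The share of common peaks depended on how an overlap was defined, and with 1 library per line a site listed in 1 line only is not shown to be unbound in the other.

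The series title names a glutaminase axis regulated by MYC, so the band of the glutaminase gene was examined next. GLS (gene ID 2744) encodes the mitochondrial enzyme that converts glutamine to glutamate. It lies in 2q32.2, with NAB1 and STAT1 as its nearest protein-coding neighbours on chromosome 2 in the GRCh38.p14 gene table. MYC peaks were found in this band in both lines, 5 in OVCAR3 and 6 in MCF7 within its 2.5 Mb (189400001 to 191900000), and 3 sites were shared. One shared site lay at 191746594 to 191746846 in OVCAR3 (23 reads, interval 14.6 to 34.5, 5.33-fold) and at 191746645 to 191746935 in MCF7 (35 reads, interval 24.4 to 48.7, 3.94-fold), with summits 84 bp apart. The strongest shared site lay at 191884947 to 191885418 in OVCAR3 (14.04-fold) and at 191884985 to 191885265 in MCF7 (8.79-fold), with summits 19 bp apart. The remaining one lay at 190649124 to 190649626 in OVCAR3 (3.83-fold) and 190649208 to 190649638 in MCF7 (6.85-fold), with summits 337 bp apart. OVCAR3 had 2 further peaks, at 191513033 to 191513240 (7.26-fold) and 191514017 to 191514219 (6.24-fold). MCF7 had 3 further peaks of 4.17-fold to 6.03-fold enrichment. Peak density in the band was 2.0 per Mb in OVCAR3 against 1.43 over chromosome 2, and 2.4 against 1.81 in MCF7. With only 5 and 6 peaks in the band, no excess over the chromosome is shown. The site at 191884947 ranked 566 of 4868 peaks in OVCAR3 and 1173 of 5979 in MCF7, above the upper quartile of enrichment in both lists. The site at 191746594 ranked 2993 and 4204, and the site at 190649124 ranked 4288 in OVCAR3 and 1168 in MCF7. Among the 3 shared sites, 1 was left at a −log10 q of at least 10 in both lists. Which gene each of these peaks lies in or near was not determined here.

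**Figure D2:**
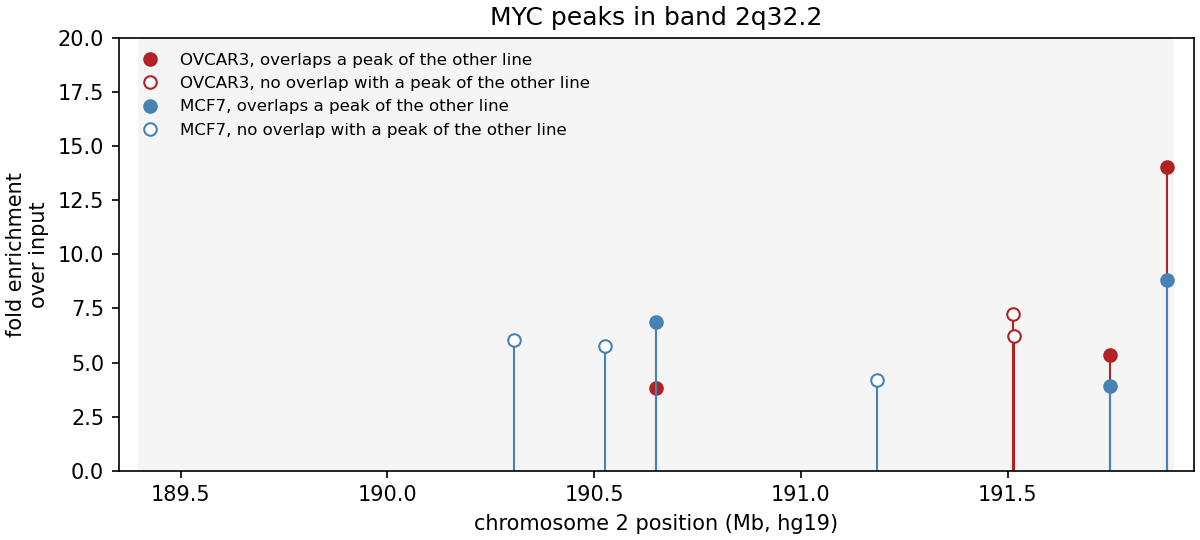
Each stem is a MYC peak in band 2q32.2 (grey), placed by its summit on chromosome 2 (x axis, Mb, hg19), with its enrichment over input as the height (y axis, fold). Filled points overlap a peak of the other line and open points do not: 3 of 5 OVCAR3 peaks (red) and 3 of 6 MCF7 peaks (blue) are filled, and the highest reach 14.04-fold and 8.79-fold.

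The last comparison asked how the peaks of each line were spread over the genome, since both lines carry gains and losses of chromosome segments. MCF7 peaks crowded into 17q22 to 17q23.2, 20q13 and 3p14, regions in which its input was also high, and OVCAR3 peaks into 11q13.4 to 11q14.1 and 19q12 to 19q13.11, where its own input was high. 17q23 and 20q13 are known as amplified in MCF7, and 19q12, the band of the cyclin E gene CCNE1, as amplified in OVCAR3. On chromosome 17 between 55 and 60 Mb there were 110 MCF7 and 13 OVCAR3 peaks, at an MCF7 input level 11.4 times the median over all its peaks. On chromosome 20 the counts were 119 and 29 between 45 and 50 Mb, 77 and 4 between 50 and 55 Mb, and 87 and 7 between 55 and 60 Mb. On chromosome 3 between 60 and 65 Mb they were 31 and 3. OVCAR3 had 48 peaks against 18 in MCF7 on chromosome 11 between 75 and 80 Mb, and 30 against 12 on chromosome 19 between 30 and 35 Mb.

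The 5 MCF7 segments of 5 Mb held 424 MCF7 peaks (7.09%, interval 6.45 to 7.77) and 56 OVCAR3 peaks (1.15%). Peaks in them had a median enrichment of 2.32-fold in MCF7, against 6.12-fold elsewhere, and 8.25% of them were shared, against 38.4% elsewhere. Both differences follow in part from the choice of segments. High input lets weaker enrichment pass, and with so few OVCAR3 peaks there only a small part of the MCF7 peaks could be shared. The ratio of the MCF7 to the OVCAR3 share of peaks was 6.16 (interval 4.66 to 8.30). Among peaks of at least 5-fold enrichment it was 0.900 (interval 0.566 to 1.43), with 41 MCF7 and 39 OVCAR3 peaks. The 2 OVCAR3 segments held 78 OVCAR3 and 30 MCF7 peaks, with a median OVCAR3 enrichment of 3.37-fold against 6.21-fold elsewhere. Their ratio of the OVCAR3 to the MCF7 share was 3.19 (interval 2.07 to 5.04), and 1.60 (interval 0.851 to 3.05) among peaks of at least 5-fold enrichment. The definition of these segments was chosen after the data had been seen.

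**Figure D3:**
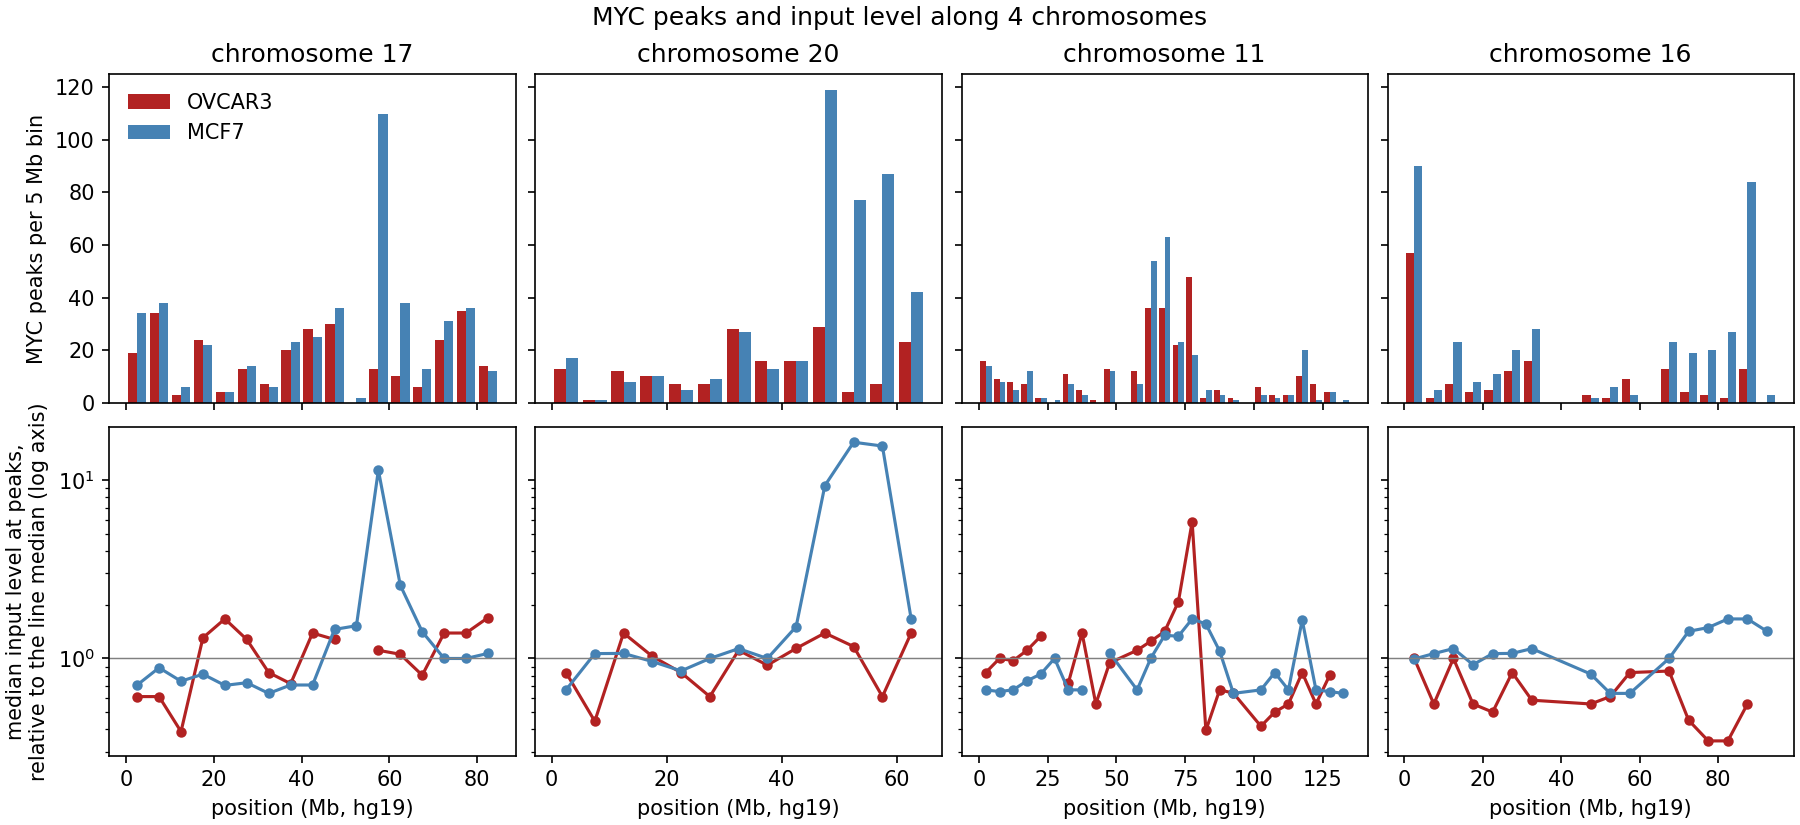
Bars in the upper panels give the number of MYC peaks per 5 Mb bin in OVCAR3 (red) and MCF7 (blue) along 4 chromosomes (x axis, Mb, hg19), and points in the lower panels the median input level at the peaks of each bin relative to the median over all peaks of the line (log axis; bins without a peak have no point). The bin of chromosome 17 with 110 MCF7 peaks has an MCF7 input of 11.4 times the median, and the bin of chromosome 11 with 48 OVCAR3 peaks an OVCAR3 input of 5.83 times the median.

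Chromosome arms differed too. Of 41 arms with at least 50 peaks in both lists together, 16q, 10p and 20q held a share of MCF7 peaks at least 1.5 times that of OVCAR3, and 18p, 5p, 22q, 4q, 9p, Xp and 3q held a share of OVCAR3 peaks at least 1.5 times that of MCF7. 16q had 187 MCF7 and 49 OVCAR3 peaks, a ratio of shares of 3.11 (interval 2.26 to 4.35), and 10p had 65 and 19, a ratio of 2.79 (interval 1.65 to 4.92). Both stayed high among peaks of at least 5-fold enrichment, at 2.61 and 2.57. The input level at their peaks differed between the lines as well, at 0.611 times the median in OVCAR3 and 1.44 times in MCF7 for 16q, and 1.06 times in MCF7 for 10p. For 10p in OVCAR3 it was 0.345 times, the lowest level that the OVCAR3 table can show and so an upper bound. Of the arms richer in OVCAR3 peaks, 18p, 5p and 4q kept an OVCAR3 share at least 1.5 times higher among such peaks. The OVCAR3 to MCF7 ratio there was 1.47 in 22q, 1.34 in 3q, 1.44 in 9p (interval 0.922 to 2.25) and 1.34 in Xp (interval 0.774 to 2.33), so that the intervals of 9p and Xp included 1. The MCF7 to OVCAR3 ratio in 20q went from 2.48 (interval 2.02 to 3.06) to 0.896 (interval 0.660 to 1.22) among such peaks. Over all peaks the MCF7 to OVCAR3 ratio was 0.512 in 22q (interval 0.387 to 0.673) and 0.386 in 18p (interval 0.207 to 0.693). In each of the 7 arms with an OVCAR3 share at least 1.5 times higher, the relative input level at peaks was higher in OVCAR3. It was 1.11 against 0.667 times the median in 22q, 1.33 against 0.781 in 18p and 0.833 against 0.666 in Xp. Arms with a smaller OVCAR3 excess went both ways. In 6q the OVCAR3 to MCF7 ratio of shares was 1.44, with input lower in OVCAR3 (0.667 against 0.781 times the median). In 10q the ratio was 1.33, with input higher in OVCAR3 (1.06 against 0.781 times the median). The MCF7 levels of 22q and Xp lie close to 0.636, the lowest that the MCF7 table can show. Whether input accounts for the larger OVCAR3 shares was not tested. The densest part of 16q was 16q24, with 93 MCF7 and 14 OVCAR3 peaks. There 7.53% of the MCF7 peaks and 7 of the 14 OVCAR3 peaks were shared. The input level was 1.67 times the median in MCF7 and 0.556 times the median in OVCAR3.

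**Figure D4:**
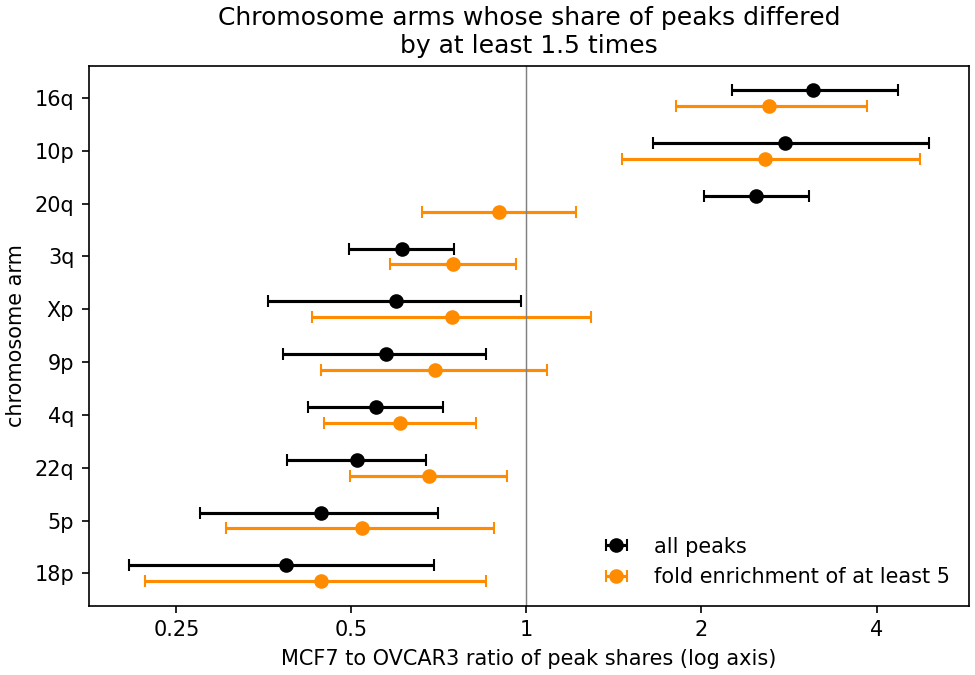
The x axis (log) gives the MCF7 to OVCAR3 ratio of the share of peaks for the 10 chromosome arms (y axis) whose shares differed by at least 1.5 times, for all peaks (black) and for peaks of at least 5-fold enrichment (orange), with 95% intervals (counting error only). Among the stronger peaks 16q stays at 2.61 and 10p at 2.57, while 20q goes from 2.48 to 0.896 and the intervals of 20q, 9p and Xp include 1.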

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

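Of 54 values under another setting, 28 stayed within the interval of the reported value (for counts, within 1.5 times), 24 moved and 2, both of 20q, crossed 1 with intervals that include 1. The settings with fold enrichment of at least 5, without the high-input segments and with a threshold of 2 times the median were chosen after the data had been seen. No replicate could be left out, and no paired analysis was possible because each group had 1 library. At a −log10 q of at least 10 the counts fell to 2551 peaks in OVCAR3 and 2954 in MCF7, by construction. The shared percentage in OVCAR3 and MCF7 was 35.9 and 29.2 with a reciprocal overlap of 0.5, 40.6 and 33.0 with summits within 200 bp, 49.7 and 40.7 for peaks within 1 kb, and 39.3 and 39.1 for the 1000 strongest peaks of each list. In MCF7 alone it moved to 37.5 at a −log10 q of at least 5, 37.8 at a −log10 q of at least 10 and 38.2 without the high-input segments. Random shifts within 500 kb gave a mean of 18.3 overlapped OVCAR3 peaks (highest 32), in place of 9.99, and were not matched on open promoters either. In 2q32.2 the shared sites went from 3 to 1 at a −log10 q of at least 10, 1 at fold enrichment of at least 5 and 0 among the 1000 strongest peaks. The percentage of peaks in high-input segments moved to 0.727 in OVCAR3 and 0.982 in MCF7 at fold enrichment of at least 5, and in MCF7 to 6.08 at a −log10 q of at least 5. It rose to 3.74 and 9.17 with a threshold of 2 times the median, by construction. The MCF7 excess in 20q was lost, with a ratio of 0.896 (interval 0.660 to 1.22) at fold enrichment of at least 5 and 0.988 (interval 0.731 to 1.34) without the high-input segments, the latter by construction. Neither shows an excess in OVCAR3. The MCF7 excess in 17q, 1.41 (interval 1.18 to 1.68), was lost under the same settings, at 1.16 (interval 0.927 to 1.46) and 1.08 (interval 0.889 to 1.32), the latter again by construction. The 22q ratio moved to 0.680 at fold enrichment of at least 5. Except where construction is named, the cause was not tested. The 16q and 10p ratios stayed within their intervals at a −log10 q of at least 5 and at fold enrichment of at least 5. Without the high-input segments they were 3.27 and 2.93, which tests nothing, since no such segment lies on either arm. Planned settings for promoters, E-box sequences, glutamine metabolism genes and gene lists were not run. Depth limits the lists at the weak end, where 9 reads made a peak in OVCAR3 and 13 in MCF7.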

Other observations

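The tests at a fold enrichment of at least 5 were chosen after the results were seen, and the others were set before theirs. A peak in 21p11.2, a band beside a centromere, had the highest input level of the MCF7 list, 136 reads. Bands that are centromeric, stalk or variable held 50 OVCAR3 and 30 MCF7 peaks.

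MCF7 peaks crowded into 5 segments of high input in 17q22 to 17q23.2, 20q13 and 3p14, with 6.16 times the OVCAR3 share. More MYC sites per DNA copy could be tested only for well-enriched sites, since a cut at 5-fold removes extra sites of weak enrichment. Well-enriched extra sites as the whole cause would have kept this excess, but at fold enrichment of at least 5 the ratio was 0.900 (interval 0.566 to 1.43), below the interval over all peaks. The same value is consistent with extra DNA copies, where more reads per locus let weak enrichment pass the threshold. Whether MYC is also enriched more strongly per copy at the 34 sites used in both lines stays open: the median MCF7 to OVCAR3 ratio of enrichment was 0.817 there (quartiles 0.719 and 1.01), against quartiles of 0.778 and 1.39 at the other 2085 pairs. Copy number itself was not measured here.

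In 16q2, only 20 of 179 MCF7 peaks overlapped an OVCAR3 peak, where 67.4 would be expected from the sharing of equally ranked MCF7 peaks over the genome, a ratio of 0.297 (interval 0.181 to 0.458). OVCAR3 had only 42 peaks in 16q2, and 20 of them were shared, against 44.4% of its whole list. In 10p, 13 of its 19 peaks were shared. So few OVCAR3 peaks limit how many MCF7 peaks can be shared, and the ratio cannot separate low sharing from a low number of OVCAR3 peaks. Weak enrichment at high MCF7 read numbers is argued against as the whole cause of the larger MCF7 share of peaks in 16q2. The ratio of shares there was 2.97 (interval 1.99 to 4.55) among peaks of at least 5-fold enrichment. Whether weak enrichment lowers the sharing was not tested, since this ratio does not measure sharing. A lower OVCAR3 input may contribute: over 186 bins of 5 Mb outside the high-input segments of both lines, with at least 10 MCF7 and 3 OVCAR3 peaks, sharing relative to expectation rose with the OVCAR3 input (Spearman's rho 0.219, permutation p = 0.00267, adjusted over 2 relations 0.00267), but rho was 0.142 (p = 0.0662) without chromosomes 10 and 16, neighbouring bins are not independent, and the relation with MCF7 input was stronger (rho -0.323, adjusted p = 4e-05). Whether low OVCAR3 input alone gives a deficit of this size stays open. The ratio of observed to expected sharing was 0.811 (interval 0.673 to 0.970) in 73 bins outside chromosome 16 with input as low as in 16q2. It lay above the bound set for this test, but these bins had to hold an OVCAR3 peak, which favours sharing. Bins of 10p were among them, so the value of 10p is not independent of this ratio. In 10p, at the lowest OVCAR3 input, the ratio was 0.523 (interval 0.278 to 0.894), which overlaps the interval of 16q2. A difference between the lines in MYC binding in 16q2 was not tested and stays open too.

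Among the 487 peaks of the strongest decile of OVCAR3, 87 had no MCF7 peak within 10 kb. High OVCAR3 input is argued against as the whole cause, since 42.5% of them (interval 32.0 to 53.6) lay at or below the median OVCAR3 input, against 39.3% of the 379 shared peaks of the same decile. Too few MCF7 reads stay open: by calculation 85 of the 87 (97.7%, interval 91.9 to 99.7) would pass the lowest MCF7 significance at 0.5 times their enrichment and the median MCF7 input, and 86 at the median input of the MCF7 peaks in the same 5 Mb bin, but the MCF7 enrichment was assumed, input at the loci themselves was not measured, and strong peaks pass almost by construction, so the bound set for this test excludes nothing. Loss of the locus in MCF7, variation between single libraries and binding in OVCAR3 cells alone were not tested and stay open.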
